A study of Mus musculus with 14 samples.

How the data were processed

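Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was made in mouse embryonic stem cells for 2 proteins, RNF2 (RING1B, the E3 ligase subunit of Polycomb repressive complex 1, which ubiquitinates histone H2A) and BAP1 (the deubiquitinase that removes this mark). All cells had been treated with 100 nM 4-hydroxytamoxifen and 10 µM emricasan, a caspase inhibitor, for 4 days, per the labels' protocols. The 14 samples comprised 7 ChIP libraries and the 7 input libraries that go with them. RNF2 ChIP had been made in 2 wild-type libraries, 2 BAP1 knockout libraries and 1 RNF2 knockout library. BAP1 ChIP had been made in 1 library of cells with the C91A form of BAP1, in which the catalytic cysteine is replaced, and in 1 library of BAP1 knockout cells. FLAG ChIP, which the protocols also mention, was not analysed here. The labels number the second library of each RNF2 genotype, and the unnumbered library was taken as the first. Nothing in them says that replicates came from separate cultures, so values measure only the spread between these samples.

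Reads were mapped with GSNAP to GRCm38 (mm10), per the submitters' processing notes; the aligner's version is not given in the sources used here. Peaks were called with MACS2 separately for each ChIP library against its input, at a q-value cutoff of 0.05, per the file headers. The headers name version 2.1.0.20150420 for the first RNF2 library of each genotype and for both BAP1 libraries, and version 2.1.1.20160309 for the second RNF2 library of each genotype and the RNF2 knockout library. Fragment length also differed per the file headers. MACS2 estimated 297 bp for the first wild-type, 323 bp for the first BAP1 knockout and 50 bp for the C91A library, which equals its tag length. A fixed extension of 100 bp was given for the second RNF2 libraries and the RNF2 knockout, and of 147 bp for the BAP1 knockout library of BAP1 ChIP. Redundant tags made up a share of 0.25, 0.28 and 0.32 in the libraries called with the later version, and 0.00 in the others. The deposited lists give, for each peak, the pileup signal at its summit, −log10 of its p-value and q-value, and its fold enrichment over the local background (a ratio). All are the authors' values. Fold enrichment was used here only to rank and describe peaks within a list, and −log10 q only as an alternative threshold. Pileup signal was not compared between libraries.

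After the authors' filtering, the RNF2 ChIP libraries held 58.4 and 149 M tags in wild type, 54.1 and 139 M in BAP1 knockout and 119 M in RNF2 knockout. Their inputs held 41.9, 162, 41.0, 155 and 161 M. The BAP1 ChIP libraries held 415 M tags in C91A cells and 32.5 M in BAP1 knockout cells, against inputs of 215 and 228 M. Depth and calling settings thus changed together between the first and second RNF2 libraries, and the results compare genotypes within each replicate number as well as across both.

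Peaks on chromosomes 1 to 19, X and Y were kept. Genes came from a RefSeq gene table of GRCm38.p6, the build of the peak lists. It held 21779 protein-coding genes after 108 entries with positions in the first 3 Mb of a chromosome other than Y, taken to lie on unplaced scaffolds, were removed. The table gives no strand, transcript start or exon. The planned windows at annotated transcription start sites were therefore replaced by windows of 1 kb on each side of both ends of a gene, and a gene counted as occupied where a peak overlapped either window by at least 1 bp. Of the occupied genes, 86.0% to 91.9% per library were occupied at 1 end only, and which end was the promoter is not known here. RNF2 regions were made by merging overlapping peaks of the 4 wild-type and BAP1 knockout libraries.

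A region or gene was called gained where both BAP1 knockout libraries and no wild-type library held a peak, and lost in the mirror case; within a replicate number, the call used that pair alone. No p-value was computed across 2 against 2 libraries, for which the smallest two-sided exact permutation p is 0.333. Associations across genes used two-sided Fisher's exact tests with conditional 95% intervals and Benjamini-Hochberg adjustment, at an adjusted threshold of 0.05. Genes are not replicates, and such a test compares the libraries, not the conditions. Shares of peaks carry Wilson 95% intervals, which cover counting error only, and were set against 100 shuffles of the peaks within chromosomes. The 16 gene lists, the tests and most alternative settings were fixed before the data were examined. A list was tested where at least 5 members lay in the background. Genes named in the text are the 10 gained, the 10 lost (there were none) and the 10 BAP1 genes with the highest fold enrichment (the lower of both libraries for gains). Added to these are the 5 highest among genes occupied in all 4 RNF2 libraries, up to 4 members per list and class by the same ranking. Also named are any member of the Polycomb, PR-DUB and intrinsic apoptosis lists, and the 4 Hox clusters. Genes sharing 1 peak counted as 1 item. Some genes that this rule picks are not reported.

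On simulated peak lists with 200 gained and 200 lost genes planted, 200 and 200 were recovered, with 201 genes called gained in all. Each planted gene held a peak in both libraries of its genotype, without the depth differences of the real libraries. The simulation therefore checks the counting only, and not how the calls behave at unequal depth. Alternatives were −log10 q of at least 5 or 10, RNF2 lists shortened to the 4038 best peaks, regions merged within 1 kb, windows of 2.5 kb, the summit in the window, genes within 10 kb or sharing a peak taken as 1 locus, no BAP1 peaks removed, and each replicate or library left out. The whole gene with 1 kb on each side, loci and strata of genes per locus for the associations of BAP1 with RNF2, the removal of the 108 entries, and the counts of genes, tests of BAP1 and tests of lists within a replicate number were added after the data were seen. Exons, introns, CpG content and the most upstream start site need a genome or transcript annotation that was not used here. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.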

Results

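RNF2 and BAP1 act in opposite directions on histone H2A ubiquitination, and the series asks where each binds in mouse embryonic stem cells and how RNF2 binding differs once BAP1 is lost. RNF2 peaks were listed for 2 wild-type, 2 BAP1 knockout and 1 RNF2 knockout library, and BAP1 peaks for 1 library of C91A cells and 1 of BAP1 knockout cells. On the main chromosomes the wild-type libraries held 4038 and 28770 RNF2 peaks, covering 6.93 and 24.5 Mb. The BAP1 knockout libraries held 7946 and 39872, covering 13.6 and 35.9 Mb. The RNF2 knockout library, with 119 M tags, listed 0 peaks. BAP1 ChIP gave 2395 peaks in C91A cells and 144 in BAP1 knockout cells. Except in RNF2 wild type and BAP1 knockout, each group had 1 library and no replicate.

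**Figure D1:**
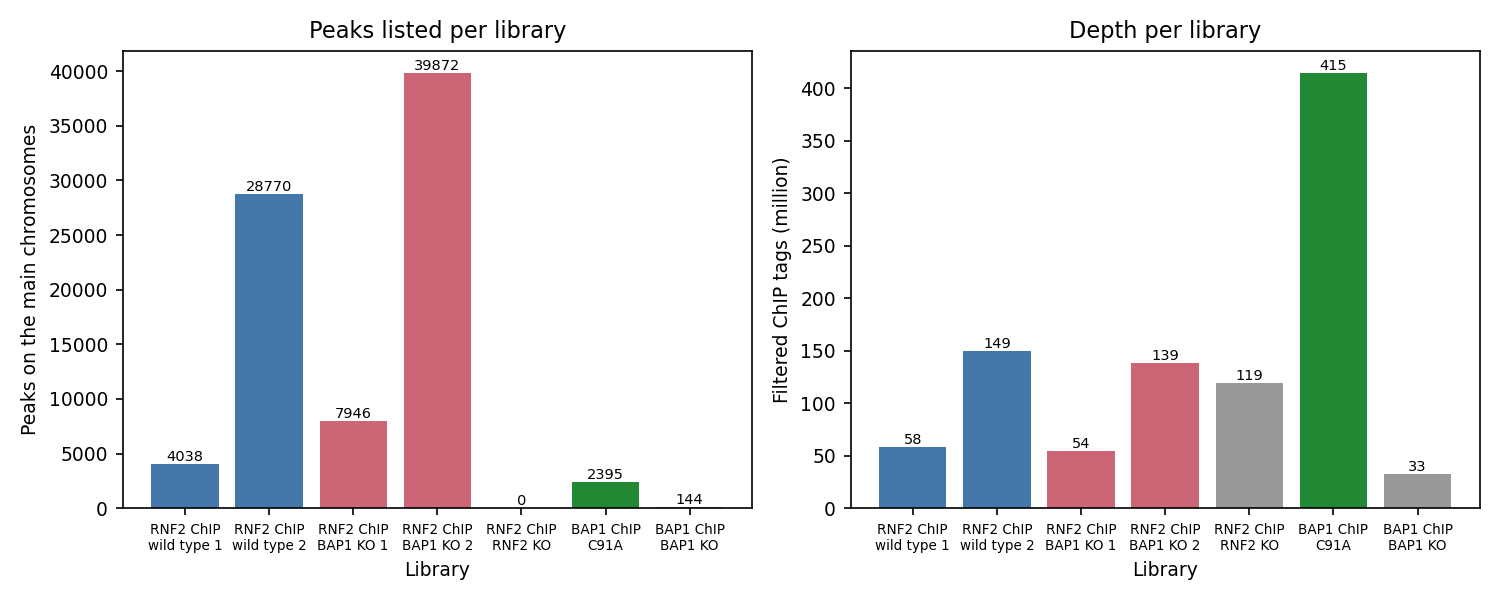
Number of peaks on the main chromosomes (left) and filtered ChIP tags in M (right) in each of the 7 ChIP libraries; bars are single libraries, without error bars. BAP1 knockout held more RNF2 peaks than wild type of the same replicate number (7946 against 4038, and 39872 against 28770) from fewer tags.

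In wild-type cells, RNF2 occupied the genes of developmental transcription factors. A peak lay at a gene end of 2421 protein-coding genes in both wild-type libraries. These were all of the 2421 genes of the first library. The second, deeper one held 10744. The strongest genes over all 4 wild-type and BAP1 knockout libraries, by the authors' fold enrichment, were Barhl2, a homeobox factor of retina and brain (chromosome 5, 106452523 to 106458166; fold enrichment 21.3 and 21.6 in wild type, 26.3 and 21.7 in BAP1 knockout) and Bmi1, a Polycomb repressive complex 1 subunit, with Gm46725 and Spag6 under the same peak. The homeobox genes Dlx6 and Six3 and the protocadherin gene Pcdh7 followed. All 39 Hox genes and 39 of 40 developmental regulators were occupied in both wild-type libraries, against 11.1% of all genes in the first library (adjusted p = 4.7e-37 and 1.3e-35, Fisher's exact test, 40 tests). Gata6, an endoderm factor, En1, a midbrain factor, and Wt1, a kidney and gonad factor, led the second list. The Hox genes lie in 4 clusters, where 1 RNF2 peak can span many genes. Their p-value treats them as separate genes, and no odds ratio with neighbouring genes as 1 locus is given for RNF2.

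Genes of lineages outside the embryo proper and of germ cells were also occupied. RNF2 lay at 7 of 14 trophoblast genes (odds ratio 8.02, 95% interval 2.40 to 26.8, adjusted exact p = 0.0014), among them Tfap2a, Hand1, Cdx2 and Gata3. It lay at 9 of 14 primitive endoderm genes (odds ratio 14.4, 4.34 to 54.9, adjusted exact p = 1.5e-05), among them Gata6, Sox17, Pdgfra and Foxa2. Of 20 germline genes, 15 held RNF2 (odds ratio 24.1, 8.33 to 84.9, adjusted exact p = 2.4e-10), led by Zcwpw1, Ddx4, Mael and Tdrkh, which act in meiosis or in the piRNA pathway. Polycomb subunit genes were occupied at 9 of 30 (odds ratio 3.44, 1.38 to 7.84, adjusted exact p = 0.013), with Bmi1, Cbx8 and Bcor among the highest. The second wild-type library alone held a peak at 28 of the 30 (odds ratio 14.4).

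Other lists were occupied rarely or at a level that did not pass the test. Ribosomal protein genes were depleted (2 of 81, Rps20 and Rpl10l; odds ratio 0.2018, adjusted exact p = 0.021), as were olfactory receptor genes (0 of 1109, adjusted p = 2.8e-57). Pluripotency genes were occupied at 2 of 20 (Tbx3 and Prdm14; adjusted exact p = 1), intrinsic apoptosis genes at 5 of 23 (adjusted p = 0.31), PR-DUB genes, which encode BAP1 and its partners, at 2 of 12 (Asxl3 and Bap1; adjusted p = 0.94), and markers of fibroblasts, a cell type often used as feeders, at 4 of 12 (adjusted p = 0.085). The remaining lists did not pass either: 1 of 49 Nduf genes of respiratory complex I (adjusted exact p = 0.086), 2 of 67 histone genes (0.076), 0 of 19 housekeeping genes (0.45) and 0 of 25 DNA replication and cell cycle genes (0.21). In the second wild-type library alone, 7 of 14 trophoblast genes became 11 and 9 of 14 primitive endoderm genes became 10. With that library alone as the wild type neither list passed the test (odds ratio 3.77 and 2.57), nor did the ribosomal genes (33 of 81, odds ratio 0.705). With the peak summit in the window the trophoblast (odds ratio 4.33, adjusted exact p = 0.089), primitive endoderm (2.95, 0.29) and ribosomal (0.273, 0.15) calls were lost too, and the odds ratio of developmental regulators fell from 317 to 5.23 (1.2e-04). The ribosomal call was lost also with −log10 q of at least 5 (0.241, 0.095) or 10 (0.173, adjusted exact p = 0.13). With neighbouring genes taken as 1 locus its odds ratio turned direction (1.72, adjusted exact p = 0.086). In that setting the intrinsic apoptosis (odds ratio 3.83, adjusted exact p = 0.0080), PR-DUB (4.97, 0.018) and fibroblast (4.97, 0.018) lists passed the test. A merged locus holds more windows and so more often a peak.

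**Figure D2:**
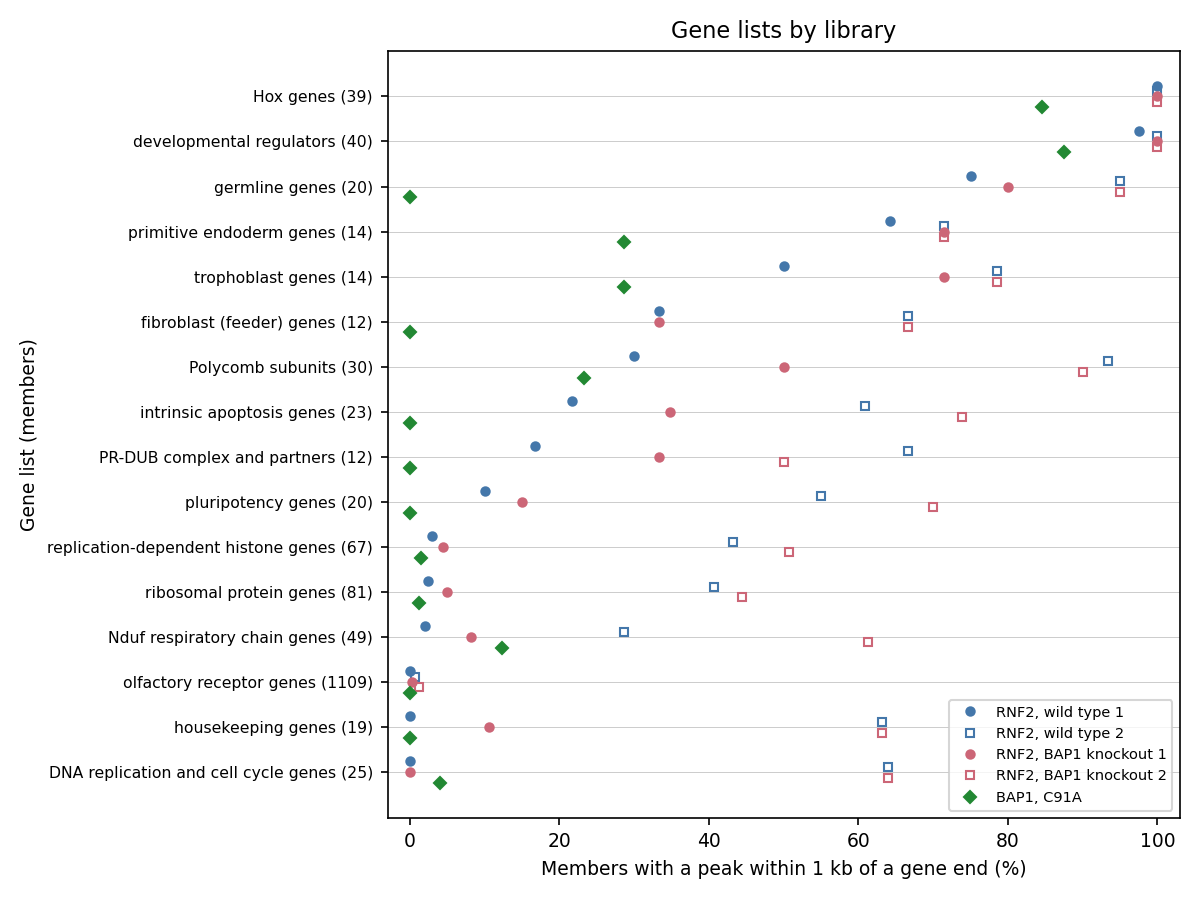
Share of the members of each of the 16 gene lists (number of members in parentheses) with a peak within 1 kb of a gene end, in percent; each marker is 1 library. Hox genes and developmental regulators are occupied at 39 of 39 and at least 39 of 40 in every wild-type and BAP1 knockout RNF2 library, while ribosomal protein genes run from 2 of 81 in the first wild-type library to 36 of 81 in the second BAP1 knockout library.

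RNF2 covered most of the length of the 4 Hox clusters in both genotypes. Over the Hoxa cluster (chromosome 6, 52145367 to 52270880, 126 kb with 10 kb on each side of the genes), RNF2 peaks covered 115 and 124 kb in wild type and 114 and 122 kb in BAP1 knockout. The Hoxb cluster (194 kb) held 117 and 145 kb against 120 and 139 kb. The Hoxc cluster (136 kb) held 117 and 131 kb against 119 and 131 kb. The Hoxd cluster (117 kb) held 86.9 and 101 kb against 89.7 and 99.0 kb. Differences between genotypes in covered length were smaller than those between the first and second library of wild type in each cluster. BAP1 peaks in C91A cells covered 14.6, 10.5, 9.88 and 12.9 kb of the clusters in the same order. Neither the RNF2 knockout nor the BAP1 knockout control held a peak there.

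**Figure D3:**
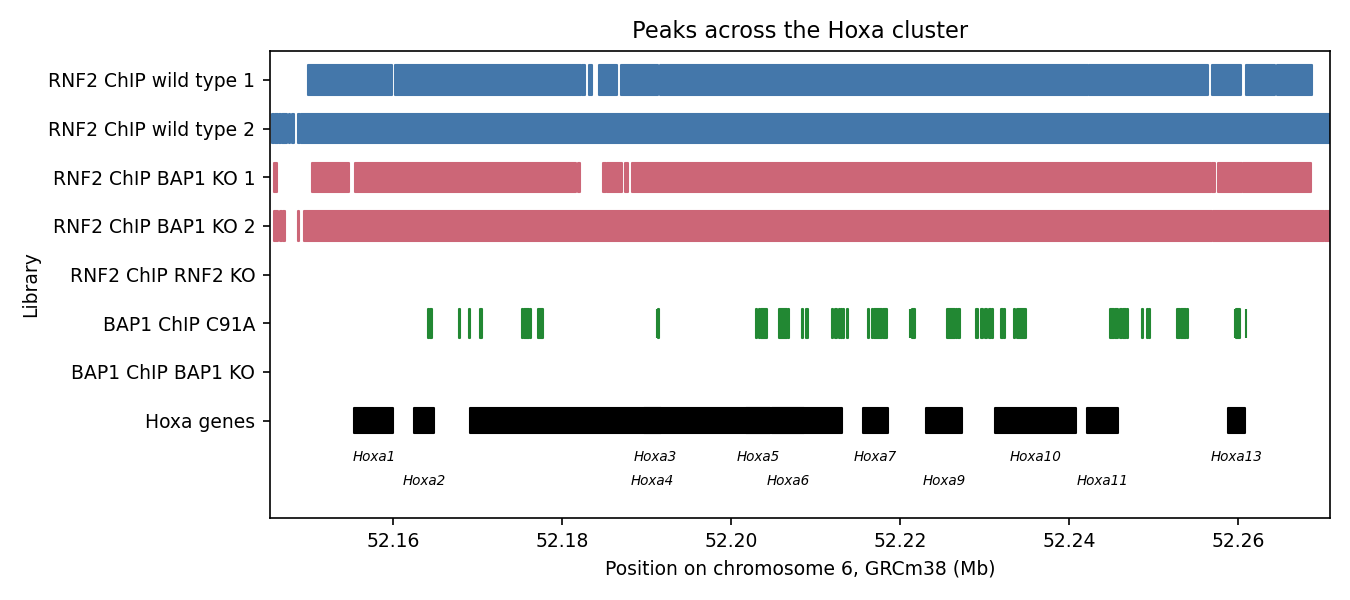
Map of the Hoxa cluster with 10 kb on each side (position on chromosome 6, GRCm38, in Mb); coloured blocks are the peaks of each library and black blocks the Hoxa genes. RNF2 peaks cover 115 and 124 kb in wild type and 114 and 122 kb in BAP1 knockout, the 70 BAP1 peaks of C91A cells cover 14.6 kb, and both knockout controls hold 0 peaks.

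Peaks of each factor lay near gene ends. At a gene end were 62.1% (Wilson 95% interval 60.6 to 63.6) and 47.9% (47.3 to 48.5) of wild-type RNF2 peaks, 64.1% (63.0 to 65.1) and 41.1% (40.6 to 41.6) of BAP1 knockout RNF2 peaks, and 51.1% (49.1 to 53.1) of BAP1 peaks in C91A cells. After shuffling the mean was 3.62% to 5.53%. Of the 144 BAP1 ChIP peaks in BAP1 knockout cells, 0.694% (0.123 to 3.83) did, a single peak, at the mitochondrial leucyl-tRNA synthetase gene Lars2.

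In BAP1 knockout, RNF2 peaks were more numerous and wider, and few genes were occupied in both BAP1 knockout libraries but in neither wild-type library. The ratio of peak numbers, BAP1 knockout over wild type, was 1.97 for the first and 1.39 for the second library of each genotype. That of covered length was 1.96 and 1.46, whereas the ratio of tags was 0.926 and 0.929. Within the first pair 2718 genes were gained and 76 lost. Within the second 2107 were gained and 288 lost. Across all 4 libraries, 36 genes and 107 regions were gained and 0 genes and 0 regions were lost. The balance depended on the library left out: 36 genes were gained and 288 lost without the first wild-type library, 2716 and 0 without the second, 2107 and 0 without the first BAP1 knockout library, and 38 and 76 without the second. With a single library left in a genotype, the rule asks for fewer peaks of that genotype. At the 3056 regions present in all 4 libraries, the median covered length was 1054 bp in wild type and 2058.5 bp in BAP1 knockout in the first pair, with 94.2% of regions wider in the knockout. It was 2949.5 and 3163.5 bp in the second, with 65.3% wider.

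The gain was mostly not the same genes in each pair. Of the 2718 genes gained in the first pair, 2680 held a peak in both of the second libraries, wild type included. Among the 11035 genes with no wild-type peak, 38 were occupied in the first BAP1 knockout library, 2107 in the second and 36 in both. If the lists were independent 7.26 would fall together (odds ratio 77.6, 19.9 to 665, p = 4.8e-24, Fisher's exact test). This test cannot show a repeated gain, because the first list was nested in the second: 5061 of its 5063 occupied genes were also in the second. The split of the 4 libraries by replicate number separated more genes than genotype did: 5355 genes were occupied in both second libraries and neither first one. With every RNF2 list shortened to its 4038 best peaks, 325 genes were gained and 108 lost across the 4 libraries, 953 gained and 431 lost in the first pair, and 643 gained and 420 lost in the second.

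Among the gained genes, the highest fold enrichment was at the metallothionein gene Mt1. Hox genes and developmental regulators all held a wild-type peak and so could not be gained. Mt1 (chromosome 8, 94178883 to 94180327) held a peak with a fold enrichment of 8.49 and 16.9 in the first and second BAP1 knockout library. It was followed by a peak shared by Glb1l and Stk16, a Golgi-associated kinase (5.77 and 16.4). Next came Ubr1, a ubiquitin ligase of the N-degron pathway (5.52 and 7.00), Flot1, a membrane scaffold protein (4.61 and 15.8), and Nupr1l (4.56 and 12.5). Then came Srrm2, a splicing factor of nuclear speckles (4.56 and 7.81), the kinesin Kifc2 (4.28 and 13.7), and Shkbp1 (3.70 and 12.9). Last were Hibch, an enzyme of valine breakdown (3.66 and 11.2), and Bcl2l14, a Bcl-2 family member (3.50 and 7.19). Of the 36 gained genes, 13 had a peak of the second wild-type library within 2.5 kb of a gene end, among them Glb1l, Stk16, Flot1, Kifc2 and Bcl2l14.

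No tested list was enriched or depleted among the 36 gained genes at an adjusted p below 0.05. With so few gained genes most intervals were wide, so these tests decide little. The odds ratio interval was 0 to 161 for pluripotency genes (9 members) and 0 to 25.5 for ribosomal protein genes (48 members). It was narrow only for olfactory receptor genes (1101 members, 0 to 0.972). Lists with under 5 members lacking a wild-type peak were not tested. Within pairs, Nduf genes were gained more often than other genes in the second (17 of 35, 48.6% against 19.0%; odds ratio 4.03, 1.95 to 8.29, adjusted exact p = 5.5e-04, 22 tests) but not in the first (3 of 48, 6.25% against 14.1%; adjusted p = 0.29). Ribosomal protein genes (2 of 79, adjusted exact p = 0.0045) and histone genes (1 of 65, adjusted p = 0.0045) were gained less often in the first pair, and not in the second (15 of 48, adjusted p = 0.11, and 11 of 38, adjusted p = 0.29). Olfactory receptor genes were gained less often in both pairs (3 of 1109, adjusted exact p = 1.3e-68, and 5 of 1101, adjusted p = 2.6e-96).

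Some Polycomb subunit genes held RNF2 in the first BAP1 knockout library and not in the first wild-type library. They were Aebp2, Ezh1 and Suz12 of Polycomb repressive complex 2, and Kdm2b, Pcgf1, Phc2 and Yaf2 of Polycomb repressive complex 1. These are 7 of 21 members against 14.0% of other genes (odds ratio 3.07, adjusted exact p = 0.075), and each also held a peak in the second wild-type library. Kdm2b, which recruits the complex to CpG islands, had a fold enrichment of 10.8 in the first BAP1 knockout library, and Yaf2 of 9.27. Ezh2, the main methyltransferase subunit, held a peak in the first wild-type library (3.77) and none in the first BAP1 knockout library. In the second libraries Ezh2 held a peak in both wild type (3.85) and BAP1 knockout (7.72). Phc1 held a peak only in the second wild-type library (2.78). Of the intrinsic apoptosis genes, Bcl2l11 (encoding BIM), Bmf and Bok were gained in the first pair (fold enrichment 14.1, 3.97 and 6.94). These also held a peak in the second wild-type library (8.57, 3.46 and 8.02). Bbc3 (encoding PUMA), Bcl2l2 and Casp9 were gained in the second pair (5.43, 5.07 and 5.79). The apoptosis list passed the test in neither pair (adjusted exact p = 0.81 in the first and 0.61 in the second). The PR-DUB genes Foxk1 and Kdm1b were gained in the first pair, but also held a peak in the second wild-type library (5.88 and 5.45). Asxl1 and Asxl2, which encode cofactors of BAP1, were lost in the second pair.

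BAP1 was mapped in C91A cells, whose protein lacks the catalytic cysteine, and found at 814 protein-coding genes, 3.74% of all. Of its 2395 peaks, 0 overlapped a peak of the BAP1 knockout control, whose library held 12.7 times fewer tags. Lars2, the only gene with a control peak, was also among the 814 BAP1 genes (fold enrichment 2.87 in C91A cells), through a separate peak. Among the strongest BAP1 genes were the forkhead gene Foxb2 (chromosome 19, 16872316 to 16873830; fold enrichment 5.89), Auh, an enzyme of leucine breakdown, and Cbx8, Nkx2-4 and Slu7, a splicing factor (5.75 each). They were followed by the zinc-finger genes Zic1 and Zic4, which share a peak (5.68), and Ccdc28a, Foxd2 and Hoxd9 (5.60 each). Auh and Slu7 held no RNF2 peak in wild type, and Ccdc28a held RNF2 in the second wild-type library but not the first.

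BAP1 shared the developmental lists with RNF2. It lay at 33 of 39 Hox genes (odds ratio 148, 60.8 to 432, adjusted exact p = 1.5e-40), led by Hoxd9, Hoxd10, Hoxb2 and Hoxd11. With neighbouring genes taken as 1 locus the odds ratio was 46.2 (adjusted exact p = 3.7e-05). It lay also at 35 of 40 developmental regulators (odds ratio 188, 73.1 to 617, adjusted exact p = 5.9e-44), led by Pax7, Nkx2-1, Wt1 and Gsc. Polycomb subunit genes held BAP1 at 7 of 30 (odds ratio 7.90, 2.85 to 19.1, adjusted exact p = 4.2e-04), among them Bmi1, Cbx8, Ezh1 and Mga. Trophoblast genes held it at 4 of 14 (Cdx2, Tfap2a, Hand1 and Gata2; odds ratio 10.3, adjusted exact p = 0.0048) and primitive endoderm genes at 4 of 14 (Sox17, Gata6, and Col4a1 with Col4a2; odds ratio 10.3, adjusted p = 0.0048). Nduf genes held BAP1 at 6 of 49 (odds ratio 3.61, 1.25 to 8.56, adjusted exact p = 0.025), led by Ndufb5, Ndufc1, Ndufaf5 and Ndufa12, none of which had a wild-type RNF2 peak. BAP1 lay at 0 of 20 germline, 0 of 20 pluripotency, 0 of 12 PR-DUB, 0 of 23 intrinsic apoptosis, 0 of 19 housekeeping and 0 of 12 fibroblast genes (adjusted exact p = 1 for each). It lay at 1 of 81 ribosomal protein genes (Rps18; 0.62), 1 of 67 histone genes (H1f10; 0.83) and 1 of 25 replication and cell cycle genes (Mcm4; 0.94), and at 0 of 1109 olfactory receptor genes (1.7e-18). With peaks of −log10 q of at least 5, the Nduf, Polycomb and primitive endoderm calls for BAP1 were lost (adjusted exact p = 0.72, 0.095 and 1), although the Polycomb odds ratio was still 7.19. With at least 10 the Polycomb call was present (odds ratio 86.2, adjusted exact p = 0.0018), and those of developmental regulators (odds ratio 29.3, adjusted p = 0.13), trophoblast, Nduf, primitive endoderm and olfactory receptor genes (odds ratio 0 and adjusted p = 1 for each) were lost. The Nduf call was lost with the whole gene as the window (odds ratio 2.96, adjusted exact p = 0.053), and the primitive endoderm call with neighbouring genes as 1 locus (odds ratio 5.52, adjusted p = 0.052). With such loci, ribosomal protein genes (odds ratio 2.41, adjusted exact p = 0.039) and replication and cell cycle genes (4.61, 0.018) passed the test for BAP1. A merged locus holds more windows and so more often a peak.

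BAP1 in C91A cells and RNF2 in wild-type cells occurred at the same genes more often than independent placement over genes would give. No library maps BAP1 in wild-type cells or RNF2 in C91A cells, so binding of both in the same cells was not measured. Of the 814 BAP1 genes, 357 (43.9%) held RNF2 in both wild-type libraries, against 9.84% of the other genes (odds ratio 7.15, 6.16 to 8.30, p = 1.7e-131, Fisher's exact test). Another 316 held RNF2 only in the second wild-type library and 141 in neither. In turn, BAP1 lay at 14.7% of genes with RNF2 in both wild-type libraries. Of the 1119 BAP1 regions left after merging within 1 kb, 61.4% and 82.4% overlapped an RNF2 peak of the first and second wild-type library, and at most 0.894% and 2.68% did so in any of 100 shuffles. Shuffled regions could fall anywhere on a chromosome, while peaks of both factors lay near gene ends. The shuffles therefore do not account for this shared location, and CpG content was not accounted for either.

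Whether RNF2 was gained at BAP1 genes depended on the pair. Of the 36 gained genes 0 held BAP1, out of 141 BAP1 genes without wild-type RNF2 (exact p = 1). The odds ratio of 0 had a wide interval (0 to 8.41) because only 36 genes were gained. This test therefore cannot decide whether gain across all 4 libraries goes with BAP1. In the first pair, RNF2 was gained at 62 of 457 BAP1 genes and 2656 of 18901 other genes without it in wild type (13.6% against 14.1%; odds ratio 0.960, 0.720 to 1.26, exact p = 0.84). In the second pair it was gained at 93 of 141 BAP1 genes and 2014 of 10894 others (66.0% against 18.5%; odds ratio 8.54, 5.94 to 12.4, exact p = 2.1e-34). Auh and Slu7 were among the 93, with RNF2 fold enrichments of 2.73 and 3.33 in the second BAP1 knockout library. The odds ratio of the second pair was 2.94 with −log10 q of at least 5 (exact p = 6.2e-05). It was 2.08 with at least 10 (exact p = 0.48), where only 20 BAP1 genes were left in all. It was 3.27 with the peak summit in the window (exact p = 1.7e-19). With neighbouring genes taken as 1 locus it was 22.2 (exact p = 4.0e-17), or 10.5 within strata of genes per locus. With all RNF2 lists shortened to 4038 peaks it was 1.10 in the second pair (p = 0.70, Fisher's exact test) and 0.295 in the first (p = 1.7e-04). With the peak summit in the window the odds ratio across all 4 libraries was 5.75 (exact p = 4.0e-04), and with neighbouring genes taken as 1 locus that of the first pair was 3.06 (exact p = 1.9e-17), or 1.502 within strata of genes per locus. RNF2 was lost less often at BAP1 genes in the first pair (4 of 357 against 72 of 2064, odds ratio 0.314, adjusted exact p = 0.021, 8 tests) and not in the second (15 of 673 against 273 of 10071, adjusted p = 0.72).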

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

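The tests of explanations below, and the alternatives for the association of RNF2 gain with BAP1 within a pair, were chosen after the patterns had been seen. Only for the depth of the BAP1 knockout control was the outcome that would decide it written down before its value was computed.

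The association of RNF2 gain with BAP1 differed between the replicate pairs: the odds ratio of the second pair was 8.90 times that of the first (95% interval 5.21 to 15.3, 2000 bootstrap draws over 12224 loci). The interval covers the draw of loci and not the spread between libraries. Besides depth, the pairs differed in peak calling version, fragment length and share of redundant tags. The backgrounds differed as well. In the first pair 457 BAP1 genes and 18901 others had no wild-type peak, and in the second 141 and 10894. The ratio therefore does not compare the same genes, and a change of background cannot be told apart from a change of association. The 93 BAP1 genes gained in the second pair, Auh and Slu7 among them, had weak RNF2 peaks. Their median lay at percentile 9.57 of the genes in the second BAP1 knockout list, against 17.2 for gained genes without BAP1 and 79.2 for genes also occupied in the first BAP1 knockout library. Since gained genes without BAP1 were weak as well, these ranks do not decide whether the association rests on weak peaks that only the deeper pair reaches. With −log10 q of at least 5 it was smaller but present (odds ratio 2.94), and with lists of 4038 peaks it was 1.10. Antibody background at these genes cannot be told apart from it either, since the RNF2 knockout library held a peak at 0 of the 93 genes but is a single library. An effect of BAP1 loss on RNF2 at these genes stays open and was not tested further.

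RNF2 peaks were more numerous in BAP1 knockout in both pairs. Deeper sequencing of the knockout libraries is argued against, as the highest tag ratio was 0.929. Of the genes gained in the first pair, 98.6% held a peak in the second wild-type library, against 33.9% of genes with no peak in either first library. They lay between the genes occupied in the first wild-type library and the rest in that list (median percentile 63.4, against 87.8 and 29.2), so they may be sites already bound in wild type that the first wild-type library did not reach. A difference in immunoprecipitation efficiency cannot be told apart from a change of RNF2 binding with BAP1 loss: 65.3% of the regions shared by all 4 libraries were wider in the knockout in the second pair, which either would give, and no spike-in was used here.

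The absence of every BAP1 peak from the BAP1 knockout control is limited by its depth. If each of the 2395 peaks kept its fold enrichment at the depth of the control, 145 (6.05%) would reach the weakest listed p of that library. Antibody background at the remaining peaks cannot be told apart from BAP1 binding, and the stated crosslinking with disuccinimidyl glutarate for C91A cells is a further difference whose effect was not tested.

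The BAP1 ChIP library of BAP1 knockout cells also held 59 peaks outside the main chromosomes, on 5 sequences and 3 of them mitochondrial, where the RNF2 knockout control held 0 and each other library between 1 and 7.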

How the results depend on the processing

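The whole-gene window, loci and their strata for the associations of BAP1 with RNF2, and every alternative for counts and associations within a replicate pair were chosen after seeing the data; the others were planned before the data were examined. Of 152 comparisons of main results with an alternative, 96 left the result as it was, and of 178 for 14 of the 15 list calls 156 did. The call of Hox genes for wild-type RNF2, and that of developmental regulators in 4 alternatives, had no finite odds ratio and were not compared. Of the 178 list comparisons, 17 lost the call and 5 turned direction. Of 322 comparisons for lists not called, 27 gave a call, and 39 turned direction without one. The association of BAP1 genes in C91A cells with RNF2 genes in wild-type cells held in every alternative (odds ratio 3.53 to 32.8). No paired analysis was possible because gained and lost regions and genes are counts of calls, which come from no test; counts within each replicate number are given in its place. Peak numbers were compared as ratios within each pair (1.97 and 1.39, SD 0.411), also without a test. The most upstream start site, exons, introns and CpG strata were not run. Where a value changed the cause was not tested, except that a merged locus holds more windows and so more often a peak.

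With −log10 q of at least 5 and of at least 10, gained regions were 197 and 232, gained genes 111 and 143, and BAP1 genes 216 and 20. At 10, lost regions were 1, wild-type RNF2 genes 1461, genes lost in the first and second pair 29 and 164, and peaks at gene ends 65.4%. The odds ratio of gain and BAP1 across 4 libraries became 4.03 at 5, and that of the second pair 2.08 at 10. For BAP1, primitive endoderm genes fell to an odds ratio of 0 at 5 and at 10, and Nduf and trophoblast genes to 0 at 10. With RNF2 lists shortened to 4038 peaks, regions gained and lost were 408 and 157, genes gained and lost 325 and 108, genes gained and lost in the first pair 953 and 431, and genes gained in the second 643. The odds ratio of gain and BAP1 was 0.295 in the first pair and 1.10 in the second. Windows of 2.5 kb gave 65.1% of peaks at gene ends and an odds ratio of 1.13 in the first pair. With the summit in the window, 70 genes were gained and 27 lost, 220 and 592 were lost in the pairs, and the odds ratios were 5.75 across 4 libraries and 1.10 in the first pair. The whole gene gave 2.39 and 1.02 for these. With 10-kb loci the first pair had 3.06, or 1.502 in strata, and ribosomal protein genes in wild type 1.72. Leaving out a replicate or library gave 107 to 19693 gained and 0 to 3939 lost regions, 36 to 2718 gained and 0 to 288 lost genes (gained with lost: 36 with 288 and 2716 with 0 without the first and second wild-type library, 2107 with 0 and 38 with 76 without the first and second BAP1 knockout library), 2421 to 10744 wild-type RNF2 genes, 47.9% to 62.1% of peaks at gene ends, and an odds ratio of gain and BAP1 of 0 to 8.54.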

Other observations

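The gene families below were chosen after the data were seen, and so were their tests.

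BAP1 peaks in C91A cells gathered at several transcription factor families that RNF2 occupied, some of whose members are also among the developmental regulators. Of 44 Fox genes 18 held BAP1 (odds ratio 18.2, 9.36 to 34.7, adjusted p = 1.4e-13 over 20 families, Fisher's exact test), of 14 Nkx genes 10 (odds ratio 65.2, adjusted p = 4.4e-11), of 9 Pax genes 6 (adjusted p = 1.4e-06), of 8 Lhx genes 5 (adjusted p = 1.2e-05) and of 19 Sox genes 6 (adjusted p = 9.6e-05). RNF2 was present in the first wild-type library at 23, 13, 8, 6 and 14 of these genes. Of 367 Krueppel-type Zfp genes, the largest family tested, 14 held BAP1 (odds ratio 1.02, adjusted exact p = 0.94). Of signalling families, RNF2 lay at 17 of 19 Wnt genes and BAP1 at 3 (Wnt5a, Wnt7b and Wnt11; adjusted exact p = 0.046), and of 22 Fgf genes RNF2 lay at 10 and BAP1 at 3 (Fgf3, Fgf8 and Fgf9; adjusted p = 0.063). The clustered gamma-protocadherin genes held RNF2 at 11 of 21 in the first wild-type and 20 in the first BAP1 knockout library, at 20 and 21 in the second libraries, and BAP1 at 0.

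BAP1 also lay at genes of mitochondrial translation. Of 77 mitochondrial ribosomal protein genes 14 held BAP1 (odds ratio 5.81, 2.99 to 10.5, adjusted exact p = 4.4e-06), among them Mrpl40, Mrps28 and Mrps15. RNF2 lay at 1 in the first wild-type, 36 in the second wild-type, 7 in the first BAP1 knockout and 53 in the second BAP1 knockout library. Some had the same BAP1 fold enrichment as an adjoining gene, as Mrpl47 and Ndufb5 did (4.06). The windows cannot assign a peak between adjoining genes, and families were not tested by locus. Proteasome genes held BAP1 at 2 of 39 (adjusted exact p = 0.73), keratin genes at 0 of 49 (adjusted p = 0.31) and vomeronasal receptor genes at 0 of 350 (adjusted p = 1.1e-05). The 141 BAP1 genes without wild-type RNF2 had BAP1 fold enrichments like those of the 357 with it in the first library (median 3.59 and 3.70), and included Abcb8, a mitochondrial transporter, Syf2, a splicing factor, Mrrf, a mitochondrial ribosome recycling factor, and Taf8.

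On the X chromosome, 0.208% of 963 genes held BAP1, and RNF2 lay at 6.33% and 20.5% in the wild-type libraries and 11.1% and 26.3% in the BAP1 knockout libraries; on chromosome 8, 7.96% of 1043 genes held BAP1.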
